A study of Mus musculus with 11 samples.

How the data were processed

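RNA from GFP-positive cells sorted from the dentate gyrus of mice at postnatal day 35 was measured on 11 Affymetrix Mouse Gene 1.0 ST arrays, 3 each for kiTbr2GFP, NesGFP and tgTbr2GFP and 2 for PomcGFP. The deposited values are 1 value per transcript-cluster probe set and array on the log2 scale, made with RMA (background correction, normalization and summary of probes), with the oligo package, per the submitters' processing notes, which give no version. The log2 scale was taken from the RMA name and from the range of the values. Array medians lay between 7.00 and 7.15; the 75th percentiles of the NesGFP arrays lay between 8.23 and 8.35 and those of the other arrays between 8.10 and 8.18.

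Of 28858 probe sets 21789 had a single gene symbol, 1621 had several and 5448 were not listed with a gene. Of those with a single symbol, 21698 matched a RefSeq gene by Entrez number, and 0 symbols needed an update. A probe set was kept when it lay above the 25th percentile of all probe sets of the array on at least 2 arrays, which left 18097. Where several kept probe sets shared a gene (868 genes), the one with the highest mean over all arrays stood for it, which gave 16527 genes. Probe sets with several or no symbols were left out of the comparisons.

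A cell-means model of the 4 lines was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, with 7 residual and 4.22 prior degrees of freedom. One fit was used because PomcGFP had 2 arrays, so its spread was pooled with that of the other lines. The comparisons were both Tbr2 lines (mean of the lines) against NesGFP, PomcGFP against both Tbr2 lines, PomcGFP against NesGFP, kiTbr2GFP against tgTbr2GFP, each Tbr2 line against NesGFP, and a moderated F test over the 4 lines. Tests were two-sided limma moderated tests, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison, with no fold threshold. Differences are log2 values of the first group minus the second.

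Of 27 gene lists (cell types, cell cycle, signalling and metabolism) 26 had enough measured genes and were tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison; an estimated correlation was the alternative. Members of a list among the genes of the pattern of both Tbr2 lines against both others were tested with a hypergeometric test, adjusted over the lists, which was chosen after seeing the data. The grouping, comparisons, tests, gene lists and alternatives were chosen before the data were examined, except those named as chosen later. Genes named in the text are, per main comparison, the 8 largest positive and 8 largest negative differences among genes past the test whose arrays did not overlap between the groups, leaving out predicted genes; a panel of stage genes; up to 2 positive and 2 negative members of each described list; sex-linked genes; and the 8 largest of each direction for the pattern of both Tbr2 lines against both others. A gene of the panel is not reported here.

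The fits were tested on simulated data. Of genes given a log2 difference of 1, the share recovered was 86.8% for both Tbr2 lines against NesGFP, 85.7% for PomcGFP against both Tbr2 lines, 60.0% for PomcGFP against NesGFP and 78.7% for kiTbr2GFP against tgTbr2GFP. At 0.5 the shares were 33.8%, 26.5%, 15.8% and 23.7%. False calls made up 3.47% to 7.01% of calls in these 4 comparisons. A list of 20 genes shifted by 0.5 was called in 20 of 20 simulations. Genes were simulated as independent of each other, so this does not test the preset correlation against the estimated one. Few of the 16527 genes were changed in each simulation.

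Alternatives were no filter (19938 genes) and a stricter filter at the 50th percentile (12321 genes), the mean of the probe sets of a gene, cyclic loess between arrays, centring each array on its median, an intensity trend with a robust prior, array weights, the replicate number as a block, a fit of the compared groups alone, an estimated correlation for the lists, and leaving out each array in turn. A covariate for the level of Y-linked genes and a fit of protein-coding genes alone were added after seeing the data. Figures and tables used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.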

Results

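Gene expression was measured on 11 Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with a set of short probes. The RNA came from green fluorescent cells sorted by flow cytometry from the microdissected dentate gyrus, the hippocampal region that keeps making neurons after birth, of mice at postnatal day 35. The cells came from 4 reporter lines. NesGFP mice (3 arrays) carry GFP for Nestin, an intermediate filament of neural stem cells. In kiTbr2GFP (3 arrays) GFP was knocked into Eomes, the gene of Tbr2, a transcription factor of intermediate neuronal progenitors, and in tgTbr2GFP (3 arrays) it is carried by a Tbr2 transgene. PomcGFP mice (2 arrays) carry GFP for Pomc, a hormone precursor gene whose reporter labels newborn granule neurons. Per the labels the RNA of the sorted cells was amplified. The number of arrays limits the precision. Nothing in the labels says that the arrays of a line came from separate animals, and p-values then measure only the spread between arrays, which may be technical. For the first and second tgTbr2GFP arrays, the sex-linked genes given below argue against repeats of the same sample.

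The lines differed in genes known to mark stages of granule neuron formation. Gfap, the intermediate filament of astrocytes and radial stem cells, stood at a log2 value of 9.89 ± 0.06 (SD, n = 3) in NesGFP and 7.16 ± 0.16 (SD, n = 3) in kiTbr2GFP, 7.61 ± 0.28 (SD, n = 3) in tgTbr2GFP and 7.39 ± 0.32 (SD, n = 2) in PomcGFP. Nes itself was at 7.35 ± 0.39 (SD, n = 3) in NesGFP and between 5.94 and 6.15 in the other lines. Eomes was at 9.98 ± 0.08 (SD, n = 3) in kiTbr2GFP and 10.18 ± 0.31 (SD, n = 3) in tgTbr2GFP, against 8.80 ± 0.38 (SD, n = 3) in NesGFP and 7.52 ± 0.23 (SD, n = 2) in PomcGFP. Calb1, the calcium-binding protein of mature granule neurons, was at 10.12 ± 0.03 (SD, n = 2) in PomcGFP. Its values were 8.86 to 9.34 in NesGFP, 6.83 to 7.78 in kiTbr2GFP and 8.03 to 8.72 in tgTbr2GFP. Calb1 passed as lower in the mean of the Tbr2 lines than in NesGFP. Pomc was at 7.25 ± 0.04 (SD, n = 2) in PomcGFP, 6.95 ± 0.12 (SD, n = 3) in NesGFP, 6.77 ± 0.20 (SD, n = 3) in kiTbr2GFP and 6.77 ± 0.28 (SD, n = 3) in tgTbr2GFP. Both PomcGFP arrays lay above the other 9, the highest of which was at 7.08, but Pomc passed in no comparison. Hes5, a Notch target, Dll1, a Notch ligand, and Calb2, calretinin of immature granule neurons, also passed in no comparison. GFP was not analysed here.

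**Figure D1:**
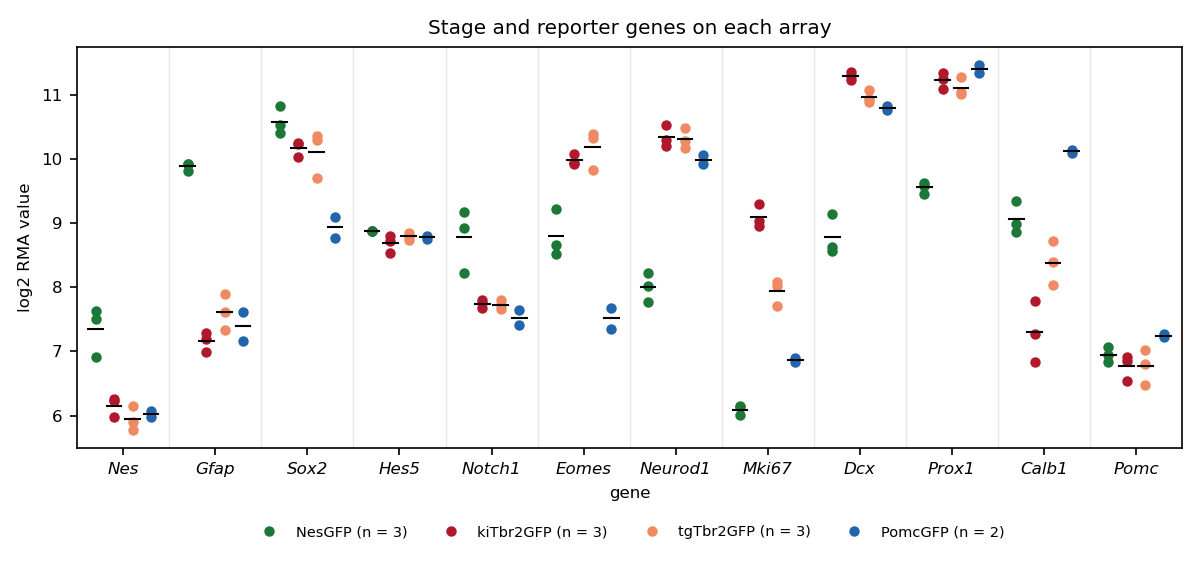
Log2 RMA values (y axis) of 12 stage and reporter genes (x axis) on each of the 11 arrays, coloured by reporter line, with black lines for group means. Gfap separated NesGFP (mean 9.89) from the other lines, Eomes was lowest in PomcGFP (mean 7.52), and Calb1 was highest there (mean 10.12).

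Across the 4 lines, 7178 of 16527 genes differed in limma's moderated F test. NesGFP arrays correlated with arrays of the other lines at r of 0.766 to 0.839 across genes, while the arrays of the other lines correlated with each other at 0.933 to 0.985. The first principal component held 68.3% of the variance and set NesGFP apart. The second held 8.88% and ran from kiTbr2GFP (15.8 to 23.5) through tgTbr2GFP (-9.51 to 4.63) to PomcGFP (-28.8 and -28.6).

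The main comparison asked which genes set cells marked by Tbr2 apart from the Nestin-reporter population, Nestin being expressed in neural stem cells. Lists of progenitor, dividing-cell and young neuron genes shifted upward as sets in the Tbr2 lines, and lists of astrocyte, vessel and oligodendrocyte lineage genes downward, with the preset correlation and not with an estimated one. For tgTbr2GFP alone the dividing-cell (adjusted p = 0.270) and progenitor lists (adjusted p = 0.0833) did not pass. Members higher and past the test in the upward lists numbered 9 of 20, 10 of 34 and 10 of 25, and the median of the dividing-cell list was 0.07 (0.12 without the first NesGFP array and 0.17 without the second). Neurod1, a transcription factor of granule neuron differentiation, was higher by 2.33 ± 0.12 (SE) on the log2 scale (adjusted p = 1.04e-07), and Dcx, the microtubule-associated protein of migrating neuroblasts, by 2.35 ± 0.13 (SE; adjusted p = 1.05e-07). Mki67, a marker of dividing cells, was higher by 2.42 ± 0.11 (SE; adjusted p = 4.99e-08) and Prox1, the granule cell fate gene, by 1.61 ± 0.10 (SE; adjusted p = 2.47e-07). Gfap differed by -2.50 ± 0.14 (SE; adjusted p = 1.36e-07), Nes by -1.30, and Notch1, the receptor that maintains stem cells, by -1.04 ± 0.17 (SE; adjusted p = 0.000365). Sox2, a stem cell transcription factor, was lower by little, at 9.70 to 10.35 on the Tbr2 arrays and 10.40 to 10.82 on the NesGFP arrays. Its call in limma ended when any of 5 arrays was left out (adjusted p = 0.0517 to 0.163).

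In all, 8089 genes passed between the Tbr2 lines and NesGFP, 3276 higher and 4813 lower in the Tbr2 lines, of which 990 and 1719 differed over 2-fold. The largest positive differences were in Mir99a (4.15), Mir690 (4.10), Thoc2l (4.05), Mirlet7c-1 (group means 8.01 and 4.01), Amy1 (3.66), Mir350 (3.62), Knl1 (3.46), a kinetochore scaffold, and Smc4 (3.34), a condensin subunit that compacts mitotic chromosomes. Whether the probe sets of these microRNA genes read mature microRNAs was not tested. Mir99a ranged from 5.33 to 8.68 on the NesGFP arrays. Mir690, Mirlet7c-1, Mir350 and Knl1 lay below the 25th percentile of the NesGFP arrays (5.90 to 6.01), so the size and order of these differences are imprecise. The largest negative ones were in Ctla2a (-4.89), Itm2a (-4.60), the myelin genes Mag (-4.48) and Opalin (-4.39), Ifitm3 (-4.29), an interferon-induced membrane protein, Myl9 (-4.29), a smooth muscle myosin light chain, Vtn (-4.01), a pericyte-expressed adhesion protein in brain, and Mgp (-3.99).

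Each gene list below was fixed before the data were examined. Of 20 intermediate progenitor genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.350 with an estimated correlation). Neurod4, a proneural transcription factor, led them at 2.72, with Elavl4, a neuronal RNA-binding protein, at 2.63, and Gadd45g was the lower one at -0.99. The median of this list was 0.16, and 0.09 without the first NesGFP array. Of 25 immature neuron genes 10 were higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 0.000955, and adjusted p = 0.160 with an estimated correlation), the lower ones being Ncam1 (-0.64) and Islr2 (-0.56). Of 34 mitotic and S-phase genes 10 were higher (10 adjusted over the list alone; adjusted p = 0.00312, and adjusted p = 0.195 with an estimated correlation), among them the mitotic motors Cenpe (2.98) and Kif11 (2.66). Of 10 Cajal-Retzius cell genes, markers of an early-born layer neuron, 7 were higher (7 adjusted over the list alone; adjusted p = 0.00163, and adjusted p = 0.195 with an estimated correlation), led by the secreted proteins Reln (2.79) and Ndnf (2.33). Of 32 axon guidance genes 16 were higher and 7 lower (16 and 8 adjusted over the list alone; adjusted p = 0.00455, and adjusted p = 0.195 with an estimated correlation), with the netrin receptor Dcc at 2.71 and Sema6a at -1.75. Ephb1 was also lower, at -1.45, but the mean of its probe sets gave 0.23 (adjusted p = 0.300).

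Of 21 neural stem cell and radial glia genes 15 were lower and 2 higher (16 and 2 adjusted over the list alone; adjusted p = 0.000325, and adjusted p = 0.195 with an estimated correlation). Etv5, a transcription factor downstream of growth factor signals, was at -2.94 and Id3, an inhibitor of differentiation, at -2.80, while Cdk6, a cell cycle kinase, was at 1.23 and Pax6 at 0.55. All 19 measured astrocyte genes were lower (19 adjusted over the list alone; adjusted p = 8.83e-11, and adjusted p = 0.126 with an estimated correlation), such as Clu at -2.75. Markers of further cell types moved the same way. All 15 endothelial genes (15 adjusted over the list alone; adjusted p = 1.17e-10, and adjusted p = 0.126 with an estimated correlation) and 11 of 12 mural cell genes (12 adjusted over the list alone; adjusted p = 1.40e-07, and adjusted p = 0.117 with an estimated correlation) were lower, including the vessel gene Emcn (-3.98), Slco1a4 (-3.98), a blood-brain barrier transporter, and the contractile gene Acta2 (-3.83). All 10 oligodendrocyte precursor genes (10 adjusted over the list alone; adjusted p = 5.49e-07, and adjusted p = 0.117 with an estimated correlation) and all 12 oligodendrocyte genes (12 adjusted over the list alone; adjusted p = 5.16e-06, and adjusted p = 0.277 with an estimated correlation) were lower, including the growth factor receptor Pdgfra (-3.14) and Gpr17 (-2.63). Of 9 meningeal fibroblast genes 5 were lower (5 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.302 with an estimated correlation), with Dcn at -2.14.

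Metabolic lists were lower in the Tbr2 lines along with the vascular and oligodendrocyte genes. All 10 cholesterol synthesis genes (10 adjusted over the list alone; adjusted p = 3.66e-05, and adjusted p = 0.126 with an estimated correlation) and 12 of 14 fatty acid genes (12 adjusted over the list alone; adjusted p = 2.75e-06, and adjusted p = 0.117 with an estimated correlation) were lower, led by the desaturases Scd2 (-2.68) and Scd1 (-2.29) and by Idi1 (-1.75) and Sqle (-1.52) of sterol synthesis. Of 12 glycolysis genes 10 were lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.000353, and adjusted p = 0.170 with an estimated correlation), with Pfkm, a phosphofructokinase, at -1.58. Of 11 interferon response genes 7 were lower (7 adjusted over the list alone; adjusted p = 0.00472, and adjusted p = 0.117 with an estimated correlation), with Ifit3 at -2.60.

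The remaining 10 lists did not pass as sets in this comparison (adjusted p = 0.0605 to 0.835), although single members did. Of 14 Notch receptors and targets 7 were lower and 2 higher (8 and 2 adjusted over the list alone), with Hey1 at -1.92, Notch2 at -1.84 and Rbpj, the DNA-binding mediator of Notch signals, at 0.58, whose call ended without the third NesGFP array (adjusted p = 0.0802). Of 17 Notch ligands and sending-cell genes 4 were lower and 1 higher (4 and 1 adjusted over the list alone), with Lfng at -1.09 and Mib1 at 0.63. Members past the test were 12 lower and 1 higher of 27 Wnt pathway genes (12 and 1 adjusted over the list alone), 10 lower and 3 higher of 20 BMP pathway genes (10 and 3), and 6 lower and 1 higher of 9 Hedgehog pathway genes (6 and 1). They included Frzb (-1.56) and Fzd3 (1.44) for Wnt, Bmp4 (-2.48) and Bmpr2 (0.76) for BMP, and Hhip (-1.13) and Cdon (1.23) for Hedgehog. The 24 mature neuron genes went both ways, 8 higher and 7 lower (8 and 9 adjusted over the list alone), with the glutamate receptor genes Gria2 at 2.34 and Grin2b at 1.86 and Ncdn at -1.65. Their median was -0.04 while the mean and test were positive. Of 13 microglia genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone), with Cd68 at 0.63 and C1qc at -0.84. Of 13 GABAergic interneuron genes 2 were higher and 3 lower (2 and 3 adjusted over the list alone), with a median of 0.17, a mean of -0.0079 and an upward test. Of 10 ependymal and choroid plexus genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone), and of 18 immediate early and dissociation stress genes 1 was higher and 8 lower (1 and 8). Without the filter on low values the Notch receptor, Wnt, BMP, Hedgehog and immediate early lists passed as sets. The erythroid list had too few measured genes for a test.

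With estimated correlations no list passed in this comparison (adjusted p = 0.117 to 0.893). The balance of directions depended on scaling: cyclic loess gave 4265 higher and 4202 lower, and centring each array on its median gave 4763 higher and 4144 lower, with the median of all genes moving from -0.02 to 0.09.

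**Figure D2:**
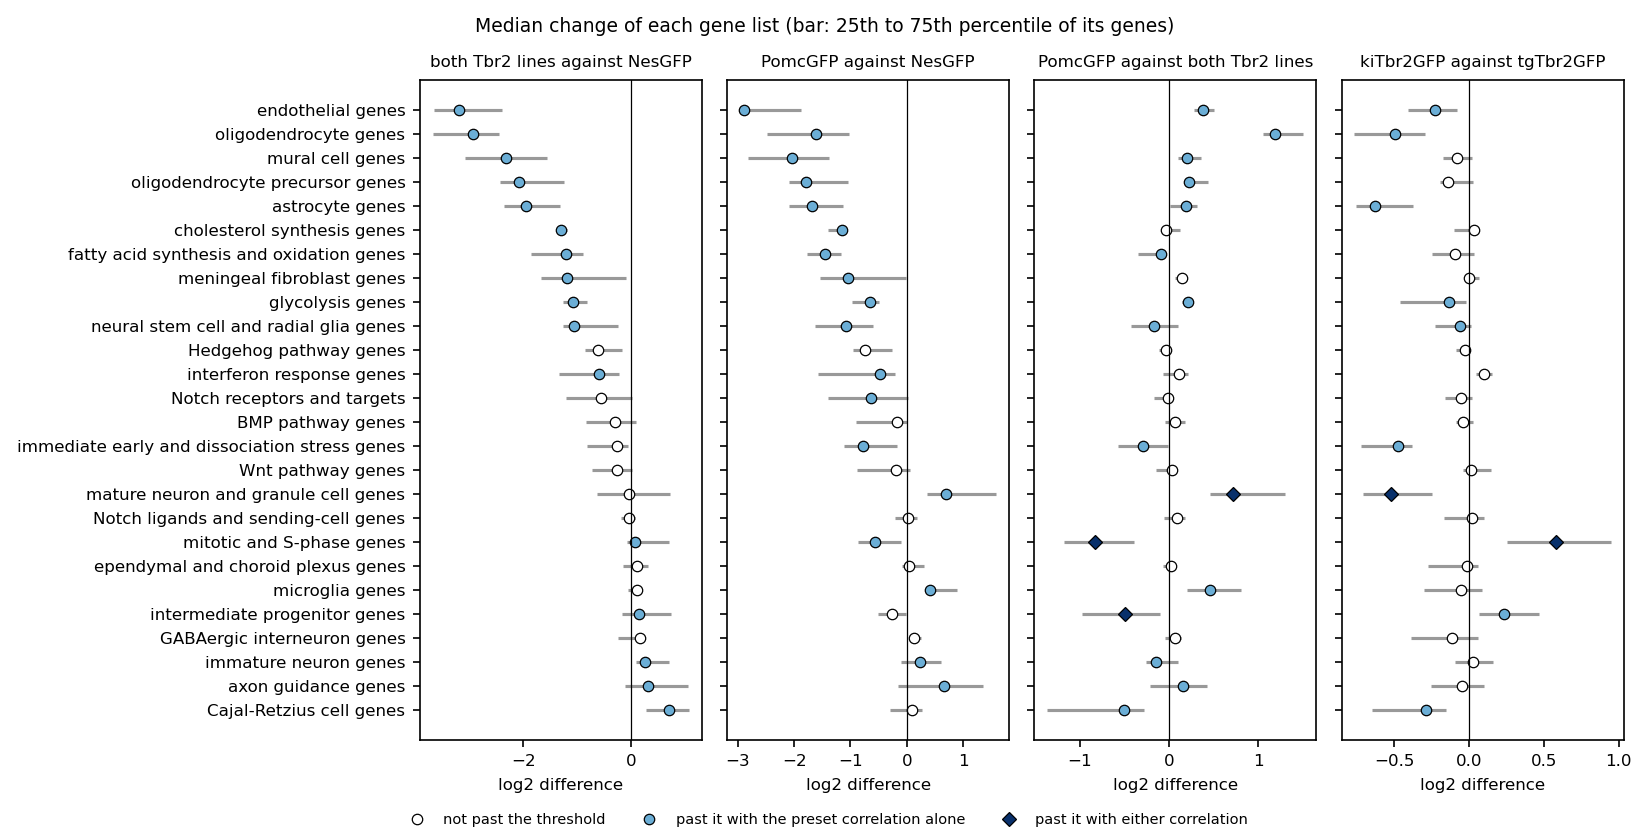
Median log2 difference of each of 26 gene lists (x axis of each panel, scales differ between panels; bars run from the 25th to the 75th percentile of the genes of the list) in 4 comparisons, with fill showing the camera result. Endothelial genes had a median of -3.20 in the Tbr2 lines against NesGFP, and mitotic genes a median of -0.83 in PomcGFP against the Tbr2 lines.

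PomcGFP against both Tbr2 lines asked how cells marked by the reporter of newborn granule neurons differ from those marked by Tbr2. The lists of dividing-cell and progenitor genes shifted downward in PomcGFP and that of mature neurons upward. Top2a, the DNA topoisomerase of dividing cells, differed by -2.73 ± 0.20 (SE; adjusted p = 7.15e-05), Mki67 by -1.65 ± 0.13 (SE; adjusted p = 7.76e-05) and Eomes by -2.56 ± 0.20 (SE; adjusted p = 7.76e-05). Calb1 was higher by 2.28 ± 0.24 (SE; adjusted p = 0.000363) and Grin2a, an NMDA receptor subunit, by 2.30 ± 0.31 (SE; adjusted p = 0.0017). Sox2, the stem cell transcription factor, differed by -1.21 (adjusted p = 0.00337), while Dcx (-0.34, adjusted p = 0.335), Neurod1 (-0.34, adjusted p = 0.330) and Prox1 (0.23, adjusted p = 0.445) did not pass.

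Here 617 genes passed, 331 higher and 286 lower in PomcGFP, of which 154 and 109 differed over 2-fold. The largest positive differences were in the adhesion gene Cdh9 (2.83), Ano3 (2.31), Grin2a, the AMPA receptor subunit Gria3 (2.29), Calb1, the cation channel Trpc6 (2.24), Ryr2 (2.21), a calcium release channel, and C1ql3 (2.18), a synaptic adhesion protein. The largest negative ones were in Ndnf (-3.10), Neurod4 (-2.82), Top2a, Knl1 (-2.64), Reln (-2.61), the chromatin protein Hmgb2 (-2.60), Eomes and Cks2 (-2.55), a cell cycle kinase subunit.

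Of 34 mitotic and S-phase genes 19 were lower (27 adjusted over the list alone; adjusted p = 1.30e-38, and adjusted p = 0.00202 with an estimated correlation), including Kif11 at -2.05. Of 24 mature neuron genes 12 were higher (20 adjusted over the list alone; adjusted p = 3.16e-22, and adjusted p = 0.00824 with an estimated correlation). Of 20 intermediate progenitor genes 8 were lower (11 adjusted over the list alone; adjusted p = 1.06e-15, and adjusted p = 0.0337 with an estimated correlation). These 3 lists were the ones that passed with either correlation.

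Other lists passed with the preset correlation alone. Of 10 Cajal-Retzius cell genes 4 were lower (5 adjusted over the list alone; adjusted p = 5.71e-09, and adjusted p = 0.0683 with an estimated correlation). Of 21 neural stem cell and radial glia genes 4 were lower (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.000459, and adjusted p = 0.285 with an estimated correlation), with Cdk6 at -1.90. Of 18 immediate early and stress genes 2 were lower, Ier2 (-0.78) and Fosb (-0.75), with 6 adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.285 with an estimated correlation). The list averaged 7.92 in PomcGFP, 7.93 in kiTbr2GFP and 8.46 in tgTbr2GFP, so its mean shift lay against tgTbr2GFP. Fosb followed this, while Ier2 was lower in PomcGFP than in either line. Of 32 axon guidance genes 6 were higher and 1 lower (9 and 4 adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.377 with an estimated correlation), with the ephrin receptors Epha7 at 1.66 and Epha5 at 1.59 and the chemokine receptor Cxcr4 at -0.68. Of 12 glycolysis genes 2 were higher, Aldoa (0.70) and Pfkp (0.61), with 2 adjusted over the list alone (adjusted p = 0.00586, and adjusted p = 0.285 with an estimated correlation). Of 14 fatty acid genes only Thrsp passed, at -0.66 (1 adjusted over the list alone; adjusted p = 0.0254, and adjusted p = 0.285 with an estimated correlation).

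Lists of some other cell types shifted upward in PomcGFP, with few members past the test and none of the lists passing with an estimated correlation. Of 13 microglia genes 4 were higher (7 adjusted over the list alone; adjusted p = 2.15e-07, and adjusted p = 0.0683 with an estimated correlation), with the protease Ctss at 1.60 and the complement gene C1qc at 1.15. Of 12 oligodendrocyte genes Mobp (1.82) and Mbp (1.46), both of myelin, were higher, with 10 adjusted over the list alone (adjusted p = 2.19e-08, and adjusted p = 0.285 with an estimated correlation). Of 19 astrocyte genes Slc4a4 (1.01) was higher, with 2 adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.556 with an estimated correlation). Astrocyte genes averaged 9.04 in PomcGFP, 9.13 in tgTbr2GFP and 8.53 in kiTbr2GFP, so their shift lay against kiTbr2GFP. Oligodendrocyte genes averaged 9.01 and 9.08 on the PomcGFP arrays, 9.26 on the first tgTbr2GFP array and 7.30 to 8.02 on the remaining Tbr2 arrays. Endothelial genes (median 0.38, adjusted p = 8.20e-05), mural cell genes (median 0.21, adjusted p = 0.0186; 0.36 without the first PomcGFP array and 0.08 without the second) and oligodendrocyte precursor genes (median 0.23, adjusted p = 0.00241) shifted upward as sets, and immature neuron genes downward (median -0.15, adjusted p = 0.0246; -0.08 without the second PomcGFP array). No member of these 4 lists passed over all genes in limma. At an unadjusted p under 0.05, 6 endothelial, 1 mural cell and 4 oligodendrocyte precursor genes were higher, and 4 immature neuron genes were lower and 1 higher. Adjusted over the list alone, 2 endothelial, 1 mural cell, 4 oligodendrocyte precursor and 0 immature neuron genes passed. With an estimated correlation these lists gave adjusted p = 0.285 for endothelial, oligodendrocyte precursor and immature neuron genes and adjusted p = 0.365 for mural cell genes. The other 10 lists, among them the GABAergic, meningeal and ependymal ones, did not pass (adjusted p = 0.259 to 0.920).

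Only 2 PomcGFP arrays entered this comparison: 180 genes passed without the first and 228 without the second. Weighting the arrays gave 1624 genes and a fit of the compared groups alone gave 1022. Without the first PomcGFP array the axon guidance (adjusted p = 0.263) and glycolysis (adjusted p = 0.0897) lists did not pass. Without the second the astrocyte (adjusted p = 0.260), immature neuron (adjusted p = 0.117), endothelial (adjusted p = 0.067), mural cell (adjusted p = 0.797) and fatty acid (adjusted p = 0.122) lists did not. The calls of Sox2 (adjusted p = 0.0831), Gria3 (adjusted p = 0.0685), Cdk6 (adjusted p = 0.0974) and Aldoa (adjusted p = 0.244) ended without the first PomcGFP array. Those of Ano3, Slc4a4, Mbp, Mobp, Ctss, C1qc, Pfkp, Epha5, Cxcr4, Ier2, Fosb and Thrsp ended without either one of the arrays, with adjusted p up to 0.377 for Pfkp. Further arrays whose loss ended the call of the astrocyte list were the second and the third of tgTbr2GFP (adjusted p from 0.0524), and the axon guidance list also lost it without the second or the third kiTbr2GFP or the first or the third tgTbr2GFP array (adjusted p from 0.0617). The fatty acid list lost it without the first kiTbr2GFP (adjusted p = 0.0557) and the first tgTbr2GFP array too (adjusted p = 0.218), and the immature neuron list without the first kiTbr2GFP array (adjusted p = 0.0762). Medians also moved. That of the neural stem cell list was -0.17, and -0.07 and -0.31 without the first and the second PomcGFP array. For glycolysis genes it was 0.22, and 0.08 and 0.38 without them, and for fatty acid genes -0.08, and -0.13 without the third kiTbr2GFP array.

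The next question was which genes were higher, or lower, in the mean of both Tbr2 lines than in NesGFP and also than in PomcGFP. The lines were not required to pass singly. There were 144 higher genes and 130 lower ones. Those higher included the progenitor genes Neurod4 and Elavl4, the kinetochore and mitotic genes Knl1, Kif11, Top2a and Cenpf, and the secreted proteins Reln and Ndnf. Those lower included the myelin genes Mobp, Mbp and Bcas1, the neuronal gene Ncdn, and Nkain2, Tmeff2, B3gnt2 and Arxes1. The PomcGFP calls of Mobp, Mbp, Bcas1, Nkain2 and Tmeff2 ended without either one of the PomcGFP arrays, with adjusted p up to 0.306 for Bcas1, and that of Arxes1 without the first (adjusted p = 0.0831). Those of Mobp, Bcas1, Nkain2 and Tmeff2 also ended without the first kiTbr2GFP, the third kiTbr2GFP or the third tgTbr2GFP array, those of Mobp and Bcas1 without the second NesGFP array, and that of Bcas1 without the second kiTbr2GFP array. Of 20 intermediate progenitor genes 7 were among the higher ones (hypergeometric test, adjusted p = 5.32e-09), of 34 mitotic and S-phase genes 8 (adjusted p = 5.32e-09), and of 10 Cajal-Retzius cell genes 4 (adjusted p = 9.66e-06). Of 24 mature neuron genes 5 were among the lower ones (adjusted p = 2.73e-05), of 12 oligodendrocyte genes 2, Mbp and Mobp (adjusted p = 0.0334), and of 12 glycolysis genes 2, Pfkp and Aldoa (adjusted p = 0.0334), whose PomcGFP calls also ended without the first PomcGFP array. Among the 5 mature neuron genes, Camk2a was at 9.70 to 10.88 in tgTbr2GFP and 10.20 to 10.45 in NesGFP. Its difference from NesGFP thus came from kiTbr2GFP (8.16 to 8.84). The hypergeometric test treats genes as independent. Eomes, whose reporter was used to sort the Tbr2 cells, was among the 7 progenitor genes. These lists had already shifted in both contrasts that define the pattern (the mature neuron list against PomcGFP alone), so the test gives no separate support.

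Because both contrasts use the Tbr2 arrays, the counts were set beside independent lists, which would share 56.7 higher and 96.4 lower genes. They were also set beside 100 simulations of unchanged groups, in which the most genes reached was 0. Those simulations held no difference between groups, so a count near 0 was built in. They cannot show how many genes contrasts with many differences would share. When the Tbr2 arrays were divided into separate sets for the contrasts, 18 divisions gave 60 to 103 higher genes (19.9 for independent lists) and 32 to 122 lower genes (34.8), and the full count was 89 without the first PomcGFP array, 121 without the second and 615 with array weights.

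PomcGFP against NesGFP set the Pomc-reporter population beside the Nestin-reporter population. Dcx was higher in PomcGFP by 2.01 ± 0.16 (SE; adjusted p = 4.40e-06), Prox1 by 1.85 ± 0.13 (SE; adjusted p = 1.86e-06), Grin2b by 2.75 ± 0.13 (SE; adjusted p = 5.19e-07) and Calb1 by 1.06 ± 0.26 (SE; adjusted p = 0.00793). Gfap differed by -2.50 ± 0.18 (SE; adjusted p = 2.29e-06), Sox2 by -1.65 ± 0.20 (SE; adjusted p = 7.87e-05), Nes by -1.33, Notch1 by -1.25 and Eomes by -1.28. In all 6591 genes passed, 2624 higher and 3967 lower in PomcGFP. The largest positive differences were in Mir340 (4.19), Thoc2l (3.79), Mir99a (3.70), Mir690 (group means 7.15 and 3.65), Mctp1 (3.48), Mir350 (3.47), Mirlet7c-1 (3.46) and AI504432 (3.43). The largest negative ones were in Ctla2a (-4.80), Myl9 (-4.34), Snord35b (-3.82), Clec2d (-3.71), Emcn (-3.56), Mgp (-3.54), Itm2a (-3.50) and Acta2 (-3.49).

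In this comparison 18 lists passed with the preset correlation, and none of them with an estimated one (adjusted p = 0.105 to 0.398). Of 24 mature neuron genes 13 were higher (13 adjusted over the list alone; adjusted p = 5.89e-07, and adjusted p = 0.105 with an estimated correlation), with Gria2 at 2.57. Of 32 axon guidance genes 18 were higher and 7 lower (19 and 7 adjusted over the list alone; adjusted p = 0.000603), with Epha7 at 2.62. Ephb1 was at -1.30, and the mean of its probe sets gave 0.33 (adjusted p = 0.279). Of 25 immature neuron genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0153), and of 13 microglia genes 8 were higher (10 adjusted over the list alone; adjusted p = 0.00123), with Ctss at 1.65 and Tyrobp, a microglial signalling adaptor, at 1.31.

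The lists that follow also passed with the preset correlation alone (adjusted p up to 0.398 with an estimated one). Of 34 mitotic and S-phase genes 17 were lower and 3 higher (19 and 4 adjusted over the list alone; adjusted p = 0.0046), with the spindle gene Tpx2 at -1.46, the replication helicase gene Mcm6 at -1.25 and Cenpe at 1.13. Of 21 neural stem cell and radial glia genes 15 were lower (16 adjusted over the list alone; adjusted p = 4.03e-07) and of 19 astrocyte genes 18 (18 adjusted over the list alone; adjusted p = 1.98e-10). All 15 endothelial genes (15 adjusted over the list alone; adjusted p = 1.98e-10), 11 of 12 mural cell genes (11; adjusted p = 1.43e-07), all 10 oligodendrocyte precursor genes (10; adjusted p = 7.23e-07), 7 of 12 oligodendrocyte genes (7; adjusted p = 0.00232) and 5 of 9 meningeal fibroblast genes (5; adjusted p = 0.0357) were lower. So were 12 of 14 fatty acid genes (13 adjusted over the list alone; adjusted p = 1.99e-07), all 10 cholesterol synthesis genes (10; adjusted p = 1.96e-05), 10 of 12 glycolysis genes (10; adjusted p = 0.00314) and 6 of 11 interferon response genes (6; adjusted p = 0.0184). Of 18 immediate early and stress genes 11 were lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.00261), with Ier3 at -2.86, and of 14 Notch receptors and targets 6 were lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0282), with Notch2 at -1.81.

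Cyclic loess gave 3326 higher and 3383 lower genes, and median centring 3462 and 3496, with the median of all genes moving from 0.005 to 0.09. The other 8 lists did not pass (adjusted p = 0.0551 to 0.750). Without 1 PomcGFP array the calls of Calb1 (adjusted p = 0.0526), Mir340 (adjusted p = 0.0608), Ctss (adjusted p = 0.0607) and Tyrobp ended, the last with adjusted p up to 0.203 over the arrays left out. That of the meningeal list ended without the first PomcGFP (adjusted p = 0.0551) and the third NesGFP array (adjusted p = 0.0557). The immature neuron median was 0.23, and 0.15, 0.13 and 0.14 without the first NesGFP, the second NesGFP and the first PomcGFP array. The Notch receptor list lost its call without the second NesGFP array (adjusted p = 0.0569).

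The last main comparison set the knock-in against the transgenic Tbr2 reporter, which mark cells through the same gene. The list of dividing-cell genes shifted upward in kiTbr2GFP and the mature neuron list downward, with either correlation, and the astrocyte list downward with the preset one alone (adjusted p = 0.0554 with an estimated one). Most members of these lists did not pass singly. Kif11 was higher by 1.71 ± 0.21 (SE; adjusted p = 0.00622), Top2a by 1.26 ± 0.20 (SE; adjusted p = 0.0151) and Mki67 by 1.16 ± 0.13 (SE; adjusted p = 0.00462). Camk2a, a synaptic kinase of excitatory neurons, differed by -1.82 ± 0.26 (SE; adjusted p = 0.00878). Eomes differed by -0.21 ± 0.20 (SE; adjusted p = 0.953), Dcx by 0.33 (adjusted p = 0.519) and Calb1 by -1.09 (adjusted p = 0.0562), and none of the 3 passed.

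Of the 16527 genes 185 passed, 72 higher and 113 lower in kiTbr2GFP. Without the third kiTbr2GFP array the balance turned to 41 higher and 28 lower. The largest positive differences were in the splicing factor Cwc22 (2.51), the meiotic helicase Hfm1 (2.14), the DNA sensor Aim2 (1.97), AA388235 (1.91), Kif11, the granzyme gene Gzma (1.65), and Ska3 (1.52) and Knl1 (1.38) of the kinetochore. The largest negative ones were in Fam183b (-2.73), n-R5s136 (-2.64), Cdh9 (-2.25), Camk2a, Mdga2 (-1.74), Gria3 (-1.74), the noncoding gene Cdr1os (-1.68) and Gdpd3 (-1.67).

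Of 34 mitotic and S-phase genes 8 were higher (20 adjusted over the list alone; adjusted p = 7.26e-27, and adjusted p = 0.00642 with an estimated correlation), with a median of 0.58. Of 24 mature neuron genes 3 were lower (13 adjusted over the list alone; adjusted p = 2.92e-13, and adjusted p = 0.0396 with an estimated correlation), with a median of -0.52 and Vsnl1, a neuronal calcium sensor, at -1.31. Of 20 intermediate progenitor genes 3 were higher (5 higher and 1 lower adjusted over the list alone; adjusted p = 6.11e-06, and adjusted p = 0.219 with an estimated correlation), including Ccnd2, a cyclin, at 0.74 and Mfap4 at 0.70. Of 19 astrocyte genes 6 were lower (13 adjusted over the list alone; adjusted p = 4.13e-20, and adjusted p = 0.0554 with an estimated correlation), with Clu at -1.17 and S100b at -1.11. Of 18 immediate early and stress genes 2 were lower, Fosb (-1.23) and Zfp36 (-0.90), with 12 adjusted over the list alone (adjusted p = 7.73e-15, and adjusted p = 0.0542 with an estimated correlation). Of 21 neural stem cell and radial glia genes only Hopx passed, at -0.66 (2 adjusted over the list alone; adjusted p = 0.0289, and adjusted p = 0.597 with an estimated correlation).

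Cajal-Retzius cell genes (median -0.29, adjusted p = 0.0014), oligodendrocyte genes (median -0.49, adjusted p = 0.00431), endothelial genes (median -0.23, adjusted p = 0.00232) and glycolysis genes (median -0.14, adjusted p = 0.0032) shifted downward as sets with no single member past the test over all genes. At an unadjusted p under 0.05, 4 Cajal-Retzius cell genes, 1 oligodendrocyte gene, 2 endothelial genes and 5 glycolysis genes were lower in limma, and 1 Cajal-Retzius cell gene was higher. Adjusted over the list alone, 4 Cajal-Retzius cell genes and 2 glycolysis genes were lower and 1 Cajal-Retzius cell gene was higher, with 0 for the oligodendrocyte and endothelial lists. With an estimated correlation the adjusted p was 0.350 for Cajal-Retzius cell and glycolysis genes, 0.628 for oligodendrocyte genes and 0.597 for endothelial genes. On the first tgTbr2GFP array the oligodendrocyte genes averaged 9.26, against 7.30 and 7.59 on the other tgTbr2GFP arrays. Without it neither the oligodendrocyte (median 0.11, adjusted p = 0.307) nor the endothelial list (median -0.05, adjusted p = 0.447) passed. The oligodendrocyte call also ended without the third kiTbr2GFP array (median -0.32, adjusted p = 0.0854), and its median was -0.74 and -0.97 without the second kiTbr2GFP and the second tgTbr2GFP array. The endothelial call also ended without the first kiTbr2GFP array (median -0.13, adjusted p = 0.0605), and its median was -0.38 without the third kiTbr2GFP or the second tgTbr2GFP array. The glycolysis median was -0.07 without the second tgTbr2GFP array. The other 16 lists did not pass (adjusted p = 0.0524 to 0.991).

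Between 68 and 85 genes passed when any kiTbr2GFP array was left out (68, 85 and 69), and 77 and 80 without the first and the third tgTbr2GFP array; the mitotic median stayed between 0.49 and 0.61 over the arrays left out. The astrocyte median was -0.42 without the first tgTbr2GFP array. Single calls that ended without at least 1 kiTbr2GFP or tgTbr2GFP array were those of Top2a (adjusted p up to 0.084), Knl1 (adjusted p = 0.0593), Aim2, Ska3, n-R5s136, Mdga2, Gria3, Cdr1os, Hopx, Clu, S100b, Ccnd2, Mfap4, Vsnl1 and Zfp36, with adjusted p up to 0.182 for Mdga2. The neural stem cell list (median -0.06) lost its call without the third tgTbr2GFP (median -0.01, adjusted p = 0.239), the first kiTbr2GFP (median -0.03, adjusted p = 0.0605), and the second or the third NesGFP array (adjusted p from 0.0533), and its median was -0.11 without the first tgTbr2GFP array. The intermediate progenitor median was 0.23, and 0.13 without the first tgTbr2GFP array. Weighting the arrays gave 1393 genes, and a fit with the level of Y-linked genes as a covariate, chosen after seeing the data, gave 194 genes (44 higher and 150 lower), of which 111 were among the 185.

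**Figure D3:**
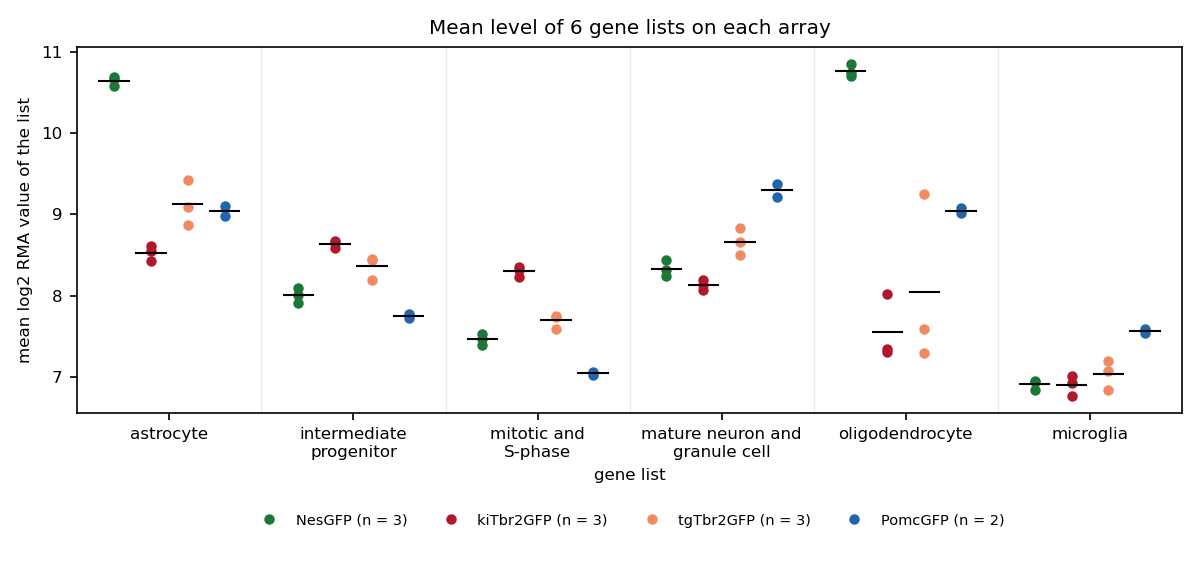
Mean log2 RMA value of the genes of each of 6 lists (x axis) on each of the 11 arrays (y axis), coloured by reporter line, with black lines for group means. Mitotic genes averaged 8.30 in kiTbr2GFP, 7.69 in tgTbr2GFP, 7.46 in NesGFP and 7.04 in PomcGFP, and 1 tgTbr2GFP array stood at 9.26 for oligodendrocyte genes.

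Against the same reference, kiTbr2GFP differed from NesGFP in 7472 genes (3002 higher and 4470 lower) and tgTbr2GFP in 6867 genes (2605 higher and 4262 lower). Of 34 mitotic and S-phase genes 14 were higher and 0 lower in kiTbr2GFP in limma (17 and 0 at an unadjusted p under 0.05; median 0.31, adjusted p = 3.58e-06, and adjusted p = 0.107 with an estimated correlation). In tgTbr2GFP they went both ways, 8 higher and 3 lower (9 and 6 unadjusted), with a median of -0.11, a mean of 0.23 and an upward test that did not pass (adjusted p = 0.270, and adjusted p = 0.549 with an estimated correlation). Intermediate progenitor genes passed for kiTbr2GFP (median 0.28, adjusted p = 0.00366, and adjusted p = 0.241 with an estimated correlation) and not for tgTbr2GFP (median 0.16, adjusted p = 0.0833). Immature neuron genes passed for both with the preset correlation alone (medians 0.26 and 0.28, adjusted p = 0.000793 and 0.00102, and adjusted p = 0.138 and 0.167 with an estimated one). Cyclic loess gave 3852 higher and 3919 lower genes for kiTbr2GFP and 3551 and 3642 for tgTbr2GFP, and median centring gave 4351 and 3800 for kiTbr2GFP and 3611 and 3614 for tgTbr2GFP.

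Sex-linked genes differed between arrays. Xist, expressed from the inactive X chromosome of females, was at 6.40 on the first tgTbr2GFP array, where the Y-linked gene Eif2s3y was at 9.76. On the second tgTbr2GFP array Xist was at 11.4 and Eif2s3y at 3.75. These opposite levels argue against the first and second tgTbr2GFP arrays being repeats of the same sample. Each of the other 9 arrays had Xist at 8.26 or above together with Eif2s3y at 6.92 or above.

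**Figure D4:**
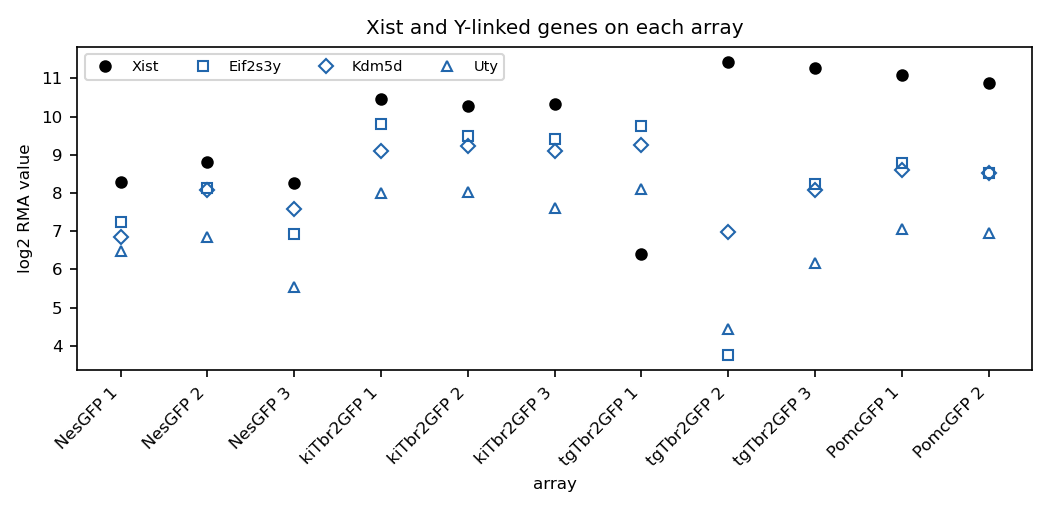
Log2 RMA values (y axis) of Xist and 3 Y-linked genes on each of the 11 arrays (x axis). The first tgTbr2GFP array had low Xist (6.40) with high Eif2s3y (9.76), and the second had high Xist (11.4) with low Eif2s3y (3.75).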

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

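The tests of the vascular and oligodendrocyte pattern and the correlation of the difference between the Tbr2 lines with the PomcGFP difference were chosen only after the result was seen, as were the Y-linked covariate as an alternative, the counts at an unadjusted p, and the lists and chromosomes set beside the difference between the Tbr2 lines.

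The Tbr2 lines differed in their effect against NesGFP, tested directly as the difference between them: 185 genes passed, the mitotic list had a median log2 difference of 0.581 and the mature neuron list of -0.521, kiTbr2GFP minus tgTbr2GFP. A covariate for Y-linked genes left the mitotic median at 0.555, which argues only weakly against the sex of the mice as the whole cause. The slope of that covariate comes from differences within lines, which were largest in tgTbr2GFP (Eif2s3y at 9.76, 3.75 and 8.24). The first tgTbr2GFP array also stood out for Ttr (12.01), so the covariate may mix sex with other traits of that array. A strain or passenger segment cannot be told apart from an effect of the line: 25 of the 185 genes had a neighbour among them, against a median of 19 for random genes (10 to 30). A count within that range was to argue against a segment, but 19.0% of random draws gave 25 or more, so it decides little. For PomcGFP against both Tbr2 lines 254 of 616 genes had such a neighbour, against a median of 193 for random genes (170 to 218) and more than in any of 10000 draws, and the cause was not tested. Cwc22, the largest positive difference (2.51), lies in a segment of variable copy number in some mouse strains. Of the 20 nearest tested neighbours of Eomes, 10 on each side of the knock-in, 0 passed between the lines in limma (lowest adjusted p = 0.0797; 1 at an unadjusted p under 0.05), which gives no sign of a segment there. The 8 mitotic genes past the test lay on 5 chromosomes, so a single segment does not hold them all. A segment that acts on genes elsewhere would give the same spread, so this does not decide. A hypothesis that stays open is that tgTbr2GFP may hold cells further along the path towards PomcGFP: across genes, which are not independent replicates, the change from kiTbr2GFP to tgTbr2GFP correlated with that from both Tbr2 lines to PomcGFP at r = 0.383 (rho = 0.212), against -0.122 to -0.0402 in simulated unchanged groups and 0.258 to 0.422 with each array left out. Of 114 genes past both tests 106 went the same way, and 6.91 shared genes would be expected of independent lists. Both contrasts use the same Tbr2 arrays, so their lists are not independent. The simulated groups held no differences and no correlation between genes, so another difference between the lines could exceed them too. Neither comparison thus singles out this hypothesis. Other lists went against it: Cajal-Retzius cell genes (-0.29, kiTbr2GFP minus tgTbr2GFP), immediate early and stress genes (-0.48) and neural stem cell and radial glia genes (-0.06) were higher in tgTbr2GFP as sets and lower in PomcGFP than in the mean of both Tbr2 lines (-0.50, -0.29 and -0.17), with the preset correlation alone. The immediate early and stress list was level in PomcGFP (7.92) and kiTbr2GFP (7.93) and higher in tgTbr2GFP (8.46). The Cajal-Retzius and stem cell lists were lower in PomcGFP than in either line. Astrocyte genes (-0.63) and oligodendrocyte genes (-0.49, and 0.11 without 1 tgTbr2GFP array), higher in tgTbr2GFP, were also higher in PomcGFP than in the mean of the Tbr2 lines as sets (0.19 and 1.19), with the preset correlation alone (adjusted p = 0.556 and 0.285 with an estimated one), and the astrocyte call ended without the second PomcGFP array. Astrocyte genes averaged 9.04 in PomcGFP, 9.13 in tgTbr2GFP and 8.53 in kiTbr2GFP. Their PomcGFP difference thus repeats the low kiTbr2GFP level and is no separate support. The knock-in of Eomes itself is confounded with the line and stays open, untested.

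Genes of vessels and of the oligodendrocyte lineage were far higher in NesGFP than in both Tbr2 lines. Unselective carry-over of all other cells is argued against by the microglia genes, whose median was 0.12 (interquartile range 0.254), and normalization by the endothelial median of -3.04 after cyclic loess. Vascular and oligodendrocyte lineage cells within the NesGFP sort cannot be told apart from expression of these genes by the cells the reporter marks, and sorting on GFP would remove cells without the reporter. The 15 most abundant genes of these lists in NesGFP, such as Slc2a1 (11.72), Vtn (11.38) and Cnp (11.81), were all lower in the Tbr2 lines, but this decides nothing, since they were taken from lists already known to be lower and by their level in NesGFP. Of 15 endothelial genes 2, of 12 mural cell genes 2 and of 12 oligodendrocyte genes 7 lay above the array median on all Tbr2 arrays too, and 1 mural cell gene stood in another list. Microglia genes were low: 3 of 13 lay above the array median on all Tbr2 arrays and 2 of 13 on all NesGFP arrays. Their probe sets did respond elsewhere, since 8 of 13 were higher in PomcGFP than in NesGFP.

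Other splits of the arrays were counted with limma. For both Tbr2 lines against NesGFP, with the 6 arrays as 1 group, the real split gave 7989 genes and the highest other of 84 splits gave 70, so 1 split reached the real count. The splits treat arrays as independent, which the labels do not say. They show that arrays differ by line, and cannot separate the reporter from anything else that follows the line. For the F test the real split gave 7178 and the highest other of 100 splits 6067. Only 1 split reached the real count, with the same limit, and the high other count points to a structure of the samples. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05, with 1 split reaching the real count in each: the real counts were 185 for kiTbr2GFP against tgTbr2GFP, 7472 for kiTbr2GFP against NesGFP and 6867 for tgTbr2GFP against NesGFP, with 0 as the highest other in each. At an unadjusted p under 0.05 the real counts were 1523, 8615 and 8116, and the highest others 1293, 1692 and 1580.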

How the results depend on the processing

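The Y-linked covariate and the fit of protein-coding genes alone were chosen after seeing the data. Of 5042 values of the 230 named-gene results past the test under the alternatives, 4810 kept direction and call, 230 lost the call and 2 reversed. Of 1380 values of the 60 list results, 1274 kept both, 104 lost the call and 2 reversed. The estimated correlation alone ended 16 of 16 list calls for both Tbr2 lines against NesGFP and 18 of 18 for PomcGFP against NesGFP. It ended 13 of 16 for PomcGFP against both Tbr2 lines and 8 of 10 for kiTbr2GFP against tgTbr2GFP. For kiTbr2GFP against tgTbr2GFP, 7 of 26 named calls ended with the Y-linked covariate, 6 with the replicate block and 4 with cyclic loess. For PomcGFP against both Tbr2 lines, 7 of 41 ended with the replicate block, and more ended when either PomcGFP array was left out. Array weights, which ran from 0.299 to 6.31, gave 1624 genes for PomcGFP against both Tbr2 lines, 1393 for kiTbr2GFP against tgTbr2GFP and 615 for the pattern of both Tbr2 lines against both others, and a fit of the compared groups alone gave 1022 for PomcGFP against both Tbr2 lines; the cause was not tested. Leaving out each array gave 180 to 806 genes for PomcGFP against both Tbr2 lines, 68 to 261 for kiTbr2GFP against tgTbr2GFP and 89 to 341 for the pattern; with 1 PomcGFP array left, that array is assumed to vary like the other groups. The replicate block gave 8418 genes for both Tbr2 lines against NesGFP, 506 for PomcGFP against both Tbr2 lines, 7124 for PomcGFP against NesGFP, 147 for kiTbr2GFP against tgTbr2GFP, 7805 and 7126 for kiTbr2GFP and tgTbr2GFP against NesGFP, 7397 for the F test and 238 for the pattern; residuals of arrays with the same number correlated at -0.106 to 0.262 across genes.

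Reversed log2 values were these, and the cause was not tested. For both Tbr2 lines against NesGFP: Notch ligands -0.0206 in the stricter filter, where the sign of the test turned, 0.0254 with cyclic loess and 0.0716 with median centring; Ephb1 0.2299 with the mean of probe sets; Hes5 0.0706 with cyclic loess; GABAergic genes 0.0255 with the Y-linked covariate, where the test turned. For PomcGFP against NesGFP: Ephb1 0.325 with the mean of probe sets and Hes5 0.136 with cyclic loess. For PomcGFP against both Tbr2 lines: Gfap -0.0102 with median centring, Nes 0.0412 with array weights and Dll1 0.0051 with the replicate block. For kiTbr2GFP against tgTbr2GFP: Pomc -0.0247 with cyclic loess and, with array weights, Pomc -0.1794, Sox2 -0.0020, Notch1 -0.0637, Neurod1 -0.1715, Ugt8a 0.2738, Slco1a4 0.0303 and oligodendrocyte genes 0.2761.

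With each array left out, results that reversed ranged as follows. PomcGFP against both Tbr2 lines: Nes -0.0737 to 0.0256, Gfap -0.2172 to 0.2307, Hes5 -0.0018 to 0.0656, Dll1 -0.1347 to 0.0020 and Calb2 -0.2787 to 0.1432. The Tbr2 lines against NesGFP: Notch ligands -0.0943 to -0.0076, where the test turned. For kiTbr2GFP against tgTbr2GFP: Sox2 -0.1507 to 0.1748, Notch1 -0.0159 to 0.0530, Dll1 -0.0194 to 0.2541, Neurod1 -0.0738 to 0.1097, Pomc -0.1454 to 0.1302, Ugt8a -1.4619 to 0.0393 and oligodendrocyte genes -0.9721 to 0.1079. The number of arrays and the spread within groups limit the precision: the median within-group SD over genes was 0.127 in kiTbr2GFP, 0.202 in NesGFP, 0.0932 in PomcGFP and 0.135 in tgTbr2GFP.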

Other observations

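The microRNA tests were chosen before their result was seen. The comparison with the median before removal of the length trend, the shortest protein-coding genes, and the values of unnamed probe sets and single genes below were chosen only after the result was seen. Of 163 microRNA genes 86 were higher and 2 lower in the Tbr2 lines, with a median log2 difference of 0.42; of 575 long noncoding genes 189 were higher and 35 lower, of 49 small nucleolar RNA genes 16 were higher and 6 lower, and of 15555 protein-coding genes 2933 were higher and 4750 lower. Only the microRNA genes were tested as a set. Whether their probe sets read mature microRNAs or longer transcripts of the same loci was not tested. In PomcGFP against NesGFP 72 microRNA genes were higher and 0 lower in limma, and 94 higher and 0 lower at an unadjusted p under 0.05. Between kiTbr2GFP and tgTbr2GFP 0 microRNA genes passed in limma, and 4 were higher and 6 lower at an unadjusted p under 0.05.

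The low level of the microRNA probe sets is argued against as the cause of their shift, since 0% of 10000 random lists matched on level reached the median, the highest reaching 0.146. The trend with genomic length that protein-coding genes show is argued against as the whole cause. It rose with length (rank correlation 0.12), while microRNA genes are short, and removing a trend on length and level left a median of 0.435, against 0.415 before. The bound set beforehand lay above the median before removal, so it could not decide. The 163 shortest protein-coding genes had a median of 0.16. None was as short as a microRNA gene (231 bases or more, against 112 at most), so a length effect in that range was not tested. No biological explanation was tested.

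Cwc22, which lies in a segment of variable copy number in some mouse strains, was at 11.38 ± 0.06 (SD, n = 3) in kiTbr2GFP and between 7.37 and 8.87 in the other lines. Ttr, the transthyretin gene of choroid plexus, was at 12.01 on the first tgTbr2GFP array and at 7.39 or below on the others. Of 4917 kept probe sets without a single gene symbol, 1902 passed the F test; 1532 were higher and 739 lower in the Tbr2 lines than in NesGFP, and 11 passed between kiTbr2GFP and tgTbr2GFP.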
